A study of Mus musculus with 9 samples.

How the data were processed

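Total RNA came from yolk sacs of mouse embryos at embryonic day 9.5 that were wild type, heterozygous or homozygous knockout for Rnh1, with 3 samples per genotype and 1 array per sample. Per the labels' protocols, 100 ng of total RNA per sample was amplified, and 5.5 µg of the sense-strand cDNA was fragmented, biotin-labelled and hybridised to an Affymetrix whole-transcript gene array. The deposited values are log2 signals per probe set, made by the authors with RMA (background correction, normalization between arrays and summary per probe set) in Affymetrix Expression Console 1.2.1.20, per the submitters' processing notes. The genome build of the array annotation is not given in the sources used here, so no coordinates are reported. For arrays, precision is limited by their number. All 9 deposited columns were used, with values from 2.46 to 13.9, and 47.2% of probe sets held a value repeated between arrays.

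The value table held 28350 probe sets, of which 21780 named 1 gene symbol, 1618 named several and 4952 named none in the probe table. Probe sets with 1 symbol covered 19933 genes, and 996 genes had more than 1 probe set, from which the probe set with the highest mean over the 9 arrays was taken. The Entrez number of 21689 probe sets was found in the reference gene table, which changed 0 symbols. Genes were tested if they lay above the 40th percentile of all probe sets of their array on at least 3 of the 9 arrays, which kept 13207 genes and left out 6726 dim ones. Probe sets that name several genes or none were left out of the comparisons and tested apart.

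Genotypes were compared with limma 3.58.1 in R 4.3.3. The deposited log2 values of all 9 arrays entered 1 linear model with genotype as the factor and no covariate, followed by empirical Bayes moderation with default settings, and contrasts were taken for KO against WT, HET against WT and KO against HET. A separate model compared KO with WT and HET taken as 1 group. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and a gene passed at an adjusted p under 0.05. Each reported fold change is a log2 difference of genotype means with its standard error from limma. For Rnh1, a two-sided exact permutation test of the arrays was added.

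A set of 26 gene lists was written before the data were examined, as were the design, the lists of alternatives and the rule for the genes to name. The lists held globins, erythroid genes, heme synthesis, blood progenitors, megakaryocyte, macrophage and granulocyte, endothelium, visceral endoderm, extraembryonic mesoderm, hypoxia, p53 targets, the integrated stress response, endoplasmic reticulum chaperones, ribosomal proteins, translation factors, the ribonuclease A family, the interferon response, inflammasome and inflammation, cell division, cholesterol synthesis, maternal decidua, trophoblast, embryo proper, adult maternal blood, sex-linked transcripts and chromosomal neighbours of Rnh1. Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. With fry each list was tested against no change, for a shift in 1 direction and for changes in either direction. List p-values were adjusted over the 26 lists of a comparison. Members past the test were counted over all genes and adjusted over the list alone. After the data were examined 10 further lists were written, and these appear among the additional observations only.

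The rule for named genes took Rnh1 first. It then took, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those that passed, or, where none passed, the 3 with the smallest unadjusted p in each direction. From each list it took up to 4 members with the smallest unadjusted p for KO against WT, whether or not they passed. Predicted genes, microRNA and small nucleolar RNA symbols with the prefixes Gm, Rik, LOC, Olfr, Vmn, Mir and Snor were counted but passed over. Genes outside the rule are said to have been named after their values were seen.

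Alternatives fixed at the same time were no filter, a filter at the array median, the mean of a gene's probe sets, arrays centred on their medians, quantile normalization, cyclic loess, a trended and robust prior, array weights, only the 2 genotypes compared, the 3 genotypes kept apart in the pooled comparison, the replicate number as a block, a change of at least 1.5-fold, an adjusted p under 0.1, and each array left out in turn. Alternatives added after the data were examined were leaving out WT 2 and KO 1 together and taking the Eif2s3y value of each array as a covariate. The overlap of comparisons that share arrays was set beside 100 simulations of unchanged groups. Splits of the arrays into groups of the same sizes were counted, 10 for 3 against 3 and 84 for 3 against 6. Intervals of list medians are 95% bootstrap intervals from 10000 resamples of the list members. They hold no spread between arrays and are too narrow where members move together. Random lists were drawn 10000 times.

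The gene test was tested on 5 simulated data sets of 13207 genes with known changes. Noise was drawn independently for each gene. Changes were put into the KO arrays only, in a far smaller share of genes than the 23.5% that passed in the real KO against WT comparison. The rates that follow hold for these settings and need not hold for the real arrays. For KO against WT it recovered 75.2% of genes changed by 0.5 log2 units, 98.5% of those changed by 1 and 100% of those changed by 2, and 6.65% of its calls were false. For KO against HET it recovered 74.6%, 98.2% and 100%, and 6% of its calls were false. HET and WT were simulated without a difference, and the 2 calls made there over the 5 data sets were both false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.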

Results

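Gene expression was measured in mouse yolk sac at embryonic day 9.5 with an Affymetrix whole-transcript gene array. The gene under study, Rnh1, encodes the ribonuclease inhibitor, a cytosolic protein that binds and blocks ribonucleases of the pancreatic type. The 9 arrays held 3 wild-type (WT), 3 heterozygous (HET) and 3 homozygous knockout (KO) samples, 1 array per sample. Values were log2 signals, with array medians from 7.07 to 7.20, and the number of arrays limited the precision. Arrays of 1 genotype correlated with r from 0.992 to 0.998 across probe sets, WT with HET arrays from 0.992 to 0.998, and KO with WT or HET arrays from 0.987 to 0.994. The first principal component held 51.8% of the variance and put the 3 KO arrays on one side, at -0.34 to -0.57, and the 6 others on the opposite side, at 0.11 to 0.38. On the next component, which held 18.7%, KO 1 (-0.72) and WT 2 (-0.41) stood apart at one end and HET 3 (0.45) lay farthest out at the other.

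The labels give neither the sex of the embryos nor whether a sample was a single yolk sac or a pool, and they do not state that the replicates came from separate animals, so the p-values measure the spread between these samples. Xist, which is transcribed from the inactive X chromosome, stood at 5.69, 10.65 and 11.00 in the WT arrays, at 5.15, 10.56 and 5.76 in HET and at 11.05, 11.06 and 11.67 in KO. The Y-linked gene Eif2s3y stood at 8.81, 8.15 and 4.34 in WT, at 8.68, 7.87 and 8.48 in HET and at 7.62, 7.27 and 4.41 in KO. Both transcripts were high in WT 2, HET 2, KO 1 and KO 2, as tissue of both sexes in a single sample would give. Xist was high on every KO array but, among the HET arrays, on HET 2 only. The sex of the tissue was thus not balanced between the genotypes, and the comparisons cannot fully separate sex from genotype.

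Rnh1 (Entrez gene 107702, probe set 10569057) was lowest in KO and intermediate in HET. Its level was 10.38 ± 0.05 in WT, 9.75 ± 0.01 in HET and 6.64 ± 0.32 in KO (log2 signal, mean ± SD, n = 3 arrays each). In KO it was at least 13.3-fold lower than in WT (log2 -3.73, SE 0.13, limma adjusted p = 4.61e-06), the smallest p of all genes tested, and at least 8.63-fold lower than in HET (log2 -3.11, adjusted p = 2.37e-05). Both folds are read as lower bounds, because KO 1 (6.28) lay below the 40th percentile of its array (6.43), the level of the filter for dim genes. HET arrays held 64.9% of the WT level (log2 -0.62, SE 0.13), which did not pass after adjustment over all genes (limma adjusted p = 0.939, the unadjusted p ranking 2 of 13207). It passed when KO 1 was left out (adjusted p = 0.0224). In every pair of genotypes the groups did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. In KO the probe set lay at percentiles 37.7 to 44.8 of its array, against 88.1 to 88.5 in WT. Neither the part of the gene that was deleted nor the place of the probe set within it is given.

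**Figure D1:**
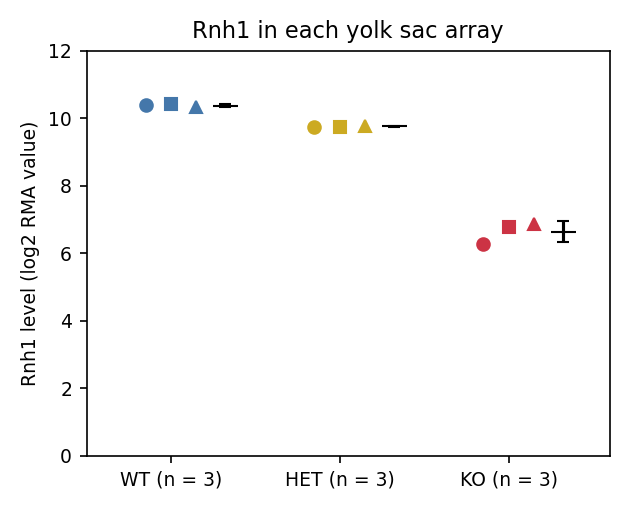
Rnh1 log2 signal (y axis, from 0) on each array by genotype (x axis), with dots for arrays and bars for the mean ± SD of 3 arrays. WT arrays sit at 10.32 to 10.42, HET at 9.75 to 9.77 and KO at 6.28 to 6.87.

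KO against WT asked what differed in the yolk sac when both copies of Rnh1 were missing. In KO 16 of 34 erythroid genes, 6 of 15 genes of heme synthesis and 14 of 38 genes of the visceral endoderm, the absorptive outer layer of the yolk sac, fell. These lists passed camera at its preset correlation and not with an estimated one (adjusted p = 0.787 for each). By fry against no change the visceral endoderm list passed (adjusted p = 0.024). The erythroid (0.108) and heme synthesis (0.0515) lists did not. The genes of the transcription factor Jun and the vasoactive peptide endothelin-1 rose. Jun rose by 1.42 ± 0.15 (log2, SE, n = 3 per genotype, limma adjusted p = 0.00131), from 8.61 ± 0.16 to 10.02 ± 0.18 (SD). Edn1, the endothelin-1 gene, rose by 1.34 ± 0.10 (adjusted p = 0.000782). Hgd, an enzyme of tyrosine breakdown, fell by 1.88 ± 0.19 (adjusted p = 0.00112), from 9.46 ± 0.26 to 7.59 ± 0.28, and Gja5, which encodes the gap junction protein connexin 40, fell by 1.67 ± 0.19, from 8.72 ± 0.27 to 7.05 ± 0.32.

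Among the other large rises were the U3 small nucleolar RNA Rnu3a (1.67 ± 0.17), the vault RNA Vaultrc5 (1.45 ± 0.14), the transcription factors Sox11 (1.40 ± 0.22) and Osr1 (1.30 ± 0.23), and the matrix protein gene Ccn1 (1.25 ± 0.17). Apela, which encodes a ligand of the apelin receptor, rose by 1.49 ± 0.34 (adjusted p = 0.0143), a call lost without WT 1 (1.38, adjusted p = 0.0548) or without WT 2 and KO 1 (1.55, adjusted p = 0.0532). Sfrp2, a secreted Wnt modulator, rose by 1.26 ± 0.30 and the immediate early gene Egr1 by 1.22 ± 0.26. Both of these calls were lost without WT 2 and KO 1 together (adjusted p = 0.0636 and 0.0637), and with array weights Egr1 stood at 0.63 and did not pass (adjusted p = 0.105). Large falls were seen in the organic cation transporters Slc22a2 (-1.70 ± 0.14) and Slc47a1 (-1.58 ± 0.13), the fatty acid carriers Cd36 (-1.66 ± 0.24) and Slc27a2 (-1.57 ± 0.21), the lectin gene Clec2h (-1.69 ± 0.19) and the aldo-keto reductase Akr1c19 (-1.47 ± 0.17). The protease gene Ctse fell by 2.03 ± 0.41 (adjusted p = 0.00954), with an adjusted p of 0.0506 without WT 2 and KO 1. For each gene named in this paragraph and the one before it, all 3 KO arrays lay beyond all 3 WT arrays, as 10% of genes do by chance in 3 against 3.

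In all, 3101 of 13207 genes tested (23.5%) differed between KO and WT by limma at an adjusted p under 0.05, with 1092 higher and 2009 lower (64.8% lower). The median size of these changes was 0.39 (log2). Among them 157 were higher and 451 lower by at least 1.5-fold, and 25 were higher and 74 lower by at least 2-fold. With each array centred on its median, 577 were higher and 2529 lower (81.4% lower), against 1471 and 1939 after quantile normalization (56.9% lower) and 1345 and 1887 with cyclic loess (58.4% lower). The count fell to 1669 without WT 1 (514 higher, 1155 lower) and to 1763 without WT 2 (628 higher, 1135 lower). Without WT 2 and KO 1, which stood apart at the same end of principal component 2, it was 2630, of which 2112 were among the 3101. Counts of list members that rose or fell in this comparison are to be read beside the 1092 higher and 2009 lower of all 13207 genes. Counts of both directions together are to be read beside the 23.5% of all genes that passed.

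Of 34 tested members of the erythroid list, 16 fell, 0 rose and 18 did not pass, against 20 that fell when adjusted over the list alone. The list median was -0.54 and 32 of 34 members lay below 0. The blood group protein gene Rhd fell by 1.26 ± 0.18 (adjusted p = 0.00258), the membrane skeleton genes Add2 and Epb42 stood at -1.02 ± 0.15 and -1.01 ± 0.18, and Bpgm, whose product sets the oxygen affinity of hemoglobin, at -0.72 ± 0.15, all past the test. The erythroid regulators Gata1 (-0.19), Klf1 (-0.43) and Tal1 (-0.13), chosen after their values were seen, did not pass. Against all other genes the list shifted down by camera at its preset correlation (adjusted p = 1.47e-04), and not with an estimated one (adjusted p = 0.787 with an estimated correlation). Tested against no change by fry, it did not pass (adjusted p = 0.108). The number that fell was 5 without WT 1, 7 without WT 3, 6 without KO 2 and 8 without KO 3. The list mean was 9.38, 9.12 and 9.28 on the WT arrays, 9.03, 9.09 and 9.43 on HET, and 9.07, 8.60 and 8.68 on KO, so that KO 1 stood nearest to WT.

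Heme synthesis had 6 of 15 members lower, 0 higher and 9 not past the test (8 lower when adjusted over the list alone), and a median of -0.33. Alas2, the first enzyme of the erythroid pathway, fell by 0.89 ± 0.18 (adjusted p = 0.00884) and Fech, the last, by 0.76 ± 0.13 (adjusted p = 0.00504). The transporters Abcb10 (-0.49) and Abcb6 (-0.33) also passed. The list passed camera at the preset correlation (adjusted p = 0.00235, against adjusted p = 0.787 with an estimated correlation), and not fry against no change (adjusted p = 0.0515). Of the 3 globin genes with a probe set of their own, the embryonic beta-like globin Hbb-y fell by 0.20 (adjusted p = 0.0481, also past the test when adjusted over the list alone). That call was lost without any 1 array other than KO 1, with adjusted p from 0.0642 to 0.128, and without KO 1 all 3 passed. Hbb-bh1 and Hba-x both stood at -0.12. The 3 globins lay between 12.79 and 13.39 on average, close to the top of the array range, and as a list they did not pass camera (median -0.12, adjusted p = 0.258).

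Among other blood lineages, 4 of 17 megakaryocyte genes fell, 1 rose and 12 did not pass (the same numbers, 4 and 1, when adjusted over the list alone), with a median of -0.21. Coagulation factor F5 (-0.55 ± 0.07, adjusted p = 0.00202) and the platelet glycoprotein Gp9 (-0.45 ± 0.09) fell, as did F2rl2 (-0.42) and Rab27b (-0.24), whereas the growth factor Pdgfb rose by 0.31. F2rl2 and Rab27b lost their calls without any single array other than KO 1 (adjusted p from 0.0536 to 0.13 and from 0.0576 to 0.14), and Pdgfb without WT 1 (0.0817) or WT 2 (0.0793). The list passed camera at the preset correlation (adjusted p = 0.0256, against adjusted p = 0.787 with an estimated correlation), and not without KO 2 (adjusted p = 0.0767). By fry against no change it shifted down (adjusted p = 0.0193). The number that fell was 7 without KO 1 and 2 without any other single array, and 0 rose without WT 1 or WT 2. Of 12 macrophage and granulocyte genes 3 fell, 0 rose and 9 did not pass (3 when adjusted over the list alone; median -0.21, camera adjusted p = 0.336). They were the mannose receptor Mrc1 (-1.29 ± 0.25, adjusted p = 0.00781), the receptor Csf1r (-0.39) and Fcgr3 (-0.83), and 1 fell without WT 2. Csf1r lost its call without WT 2 (adjusted p = 0.0554) and Fcgr3 without WT 1 (0.051) or WT 2 (0.0589). Of 22 blood progenitor genes, 20 did not pass, 1 rose and 1 fell, also when adjusted over the list alone (median 0.05, camera adjusted p = 0.638). Gata2 stood at 1.08 (adjusted p = 0.0234) and Ikzf1 at -0.70 (adjusted p = 0.0195). Gata2 lost its call without WT 1 (adjusted p = 0.0744), WT 3 (0.0611) or KO 2 (0.0611), and Ikzf1 without WT 1 (0.069), WT 3 (0.0554), KO 2 (0.0658) or KO 3 (0.0603), while a second member rose without KO 3.

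**Figure D2:**
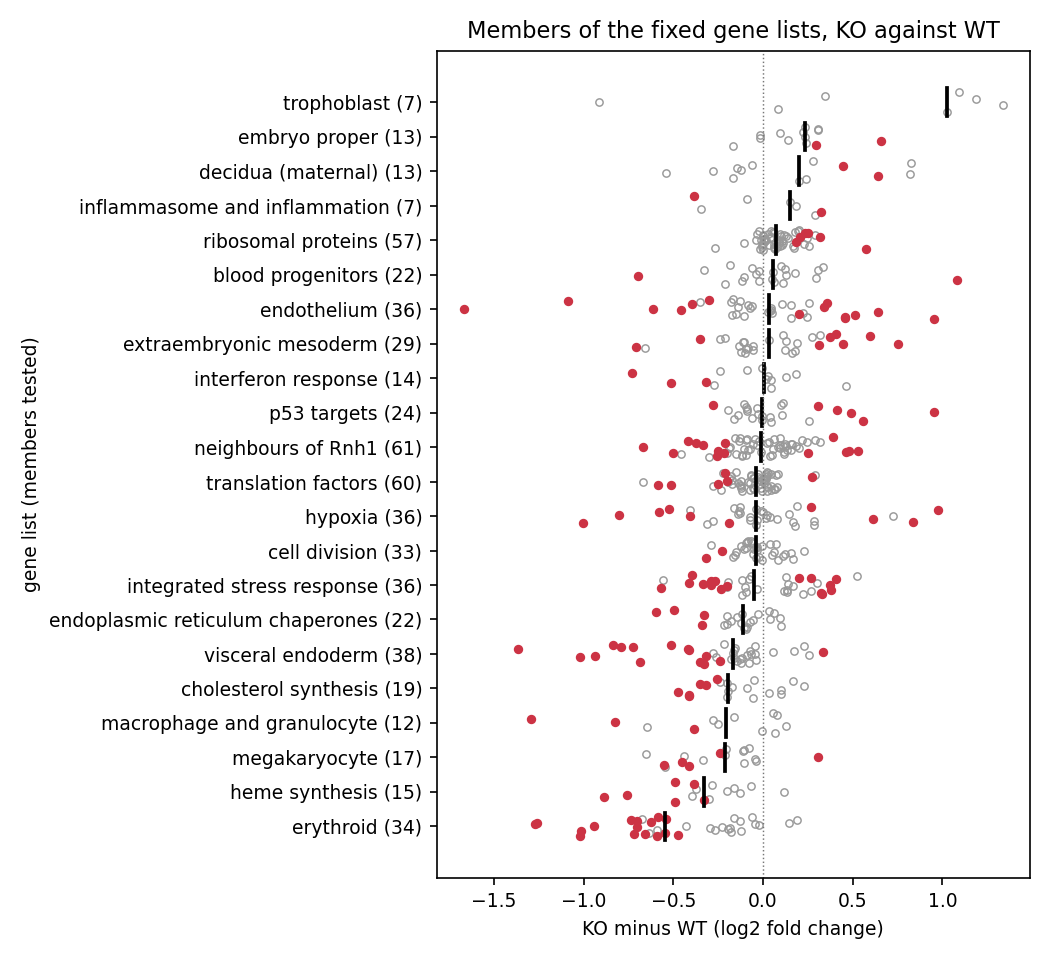
Log2 fold change of KO against WT (x axis) of every tested member of the 22 lists with at least 7 tested members (y axis, sorted by median), with red points past the test, open grey points not past it and black lines for list medians. The erythroid median is -0.54 with 16 of 34 members lower, and the visceral endoderm median is -0.17 with 14 of 38 lower.

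Of 38 visceral endoderm genes 14 fell, 1 rose and 23 did not pass (again 14 and 1 when adjusted over the list alone), with a median of -0.17. The iron exporter gene Slc40a1 fell by 0.79 ± 0.08 (adjusted p = 0.00127), from 11.01 ± 0.15 to 10.21 ± 0.07 (SD, n = 3), and the apolipoprotein gene Apoa4 by 0.69 ± 0.08 (adjusted p = 0.00132). The zinc importer gene Slc39a4 (-0.72 ± 0.09) and the fibrinogen chain gene Fga (-1.02 ± 0.13) fell as well. Ihh, which encodes a hedgehog ligand and was named after its value was seen, rose by 0.33 (adjusted p = 0.0385). It lost its call without any single array other than KO 3 (adjusted p from 0.0527 to 0.121), and 0 members rose without any WT array, any HET array or KO 1. The list shifted down by camera at the preset correlation (adjusted p = 1.47e-04, against adjusted p = 0.787 with an estimated correlation). By fry against no change it shifted down as well (adjusted p = 0.024). List means were 11.25, 11.30 and 11.23 in WT, 11.31, 11.28 and 11.17 in HET, and 11.03, 11.03 and 10.90 in KO.

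Endothelial genes changed in both directions. Of 36 members 8 rose, 6 fell and 22 did not pass (9 and 6 when adjusted over the list alone). Etv2, a regulator of early endothelial fate, rose by 0.64 ± 0.09 (adjusted p = 0.00202), Egfl7 by 0.52 ± 0.07 and the apelin gene Apln by 0.95 ± 0.14, while Gja5 was among the falls. The list did not shift as a whole (camera adjusted p = 0.533), with a median of 0.03 and a mean of -0.02, and fry for changes in either direction gave an adjusted p of 2.87e-07. That fry test is against no change, while 23.5% of all genes passed by limma. It also passed for lists such as cell division (adjusted p = 9.02e-04) and translation factors (2.33e-04). It therefore does not set the lists of this paragraph apart. The number that rose was 5 without any of HET 1, HET 2, HET 3, WT 1, WT 3 or KO 2. Of 29 genes of the extraembryonic mesoderm 6 rose, 2 fell and 21 did not pass (6 and 3 when adjusted over the list alone; median 0.03, camera adjusted p = 0.242, fry against no change in either direction 2.87e-07). The transcription factors Hand1 (0.75 ± 0.10, adjusted p = 0.00184), Twist1 (0.59 ± 0.07) and Hand2 (0.45 ± 0.06) rose. The falls were Postn (-0.35) and the collagen gene Col4a2 (-0.71), the latter named after its value was seen, at 10.16 ± 0.50 in WT, 9.48 ± 0.06 in HET and 9.46 ± 0.05 in KO (SD, n = 3). Postn lost its call without WT 2 (adjusted p = 0.0535) or KO 2 (0.0502), and Col4a2 without any single array other than WT 2 or HET 3 (0.0532 to 0.102). On the same arrays the mean of the trophoblast list was 7.52 to 7.59 in WT and 7.59 to 8.82 in KO. Without WT 1 the number that rose was 3, and the number that fell was 1 without WT 1, WT 3, HET 1, HET 2 or KO 3 and 0 without KO 2.

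Of 57 ribosomal protein genes 6 rose, 0 fell and 51 did not pass (3 rose when adjusted over the list alone), with a median of 0.07, or 0.01 when arrays were centred on their medians, where 2 rose and 1 fell. Rpl12 rose by 0.57 ± 0.11 (adjusted p = 0.00683) and Rps14 by 0.32 ± 0.07 (adjusted p = 0.0124). Relative to other genes the list shifted up by camera at the preset correlation (adjusted p = 4.91e-04, against adjusted p = 0.787 with an estimated correlation). By fry against no change it shifted up as well (adjusted p = 0.00976). The number that rose was 3 without WT 1 and 2 without WT 2 or WT 3, and 1 fell without WT 3. Of 60 translation factor genes, a list caught by symbol that also holds the Eif2ak kinases, 5 fell, 1 rose and 54 did not pass (1 and 0 when adjusted over the list alone; median -0.04, camera adjusted p = 0.336). Eif2ak3, a kinase of the unfolded protein response, fell by 0.59 ± 0.11 (adjusted p = 0.00691). The other falls were Eif2b3 (-0.25), Eif3c (-0.20), Eif2ak2 (-0.51) and, named after its value was seen like the rise of Eif4a2 (0.27), Eif5a2 (-0.21). Eif4a2 lost its call without WT 1, WT 2, WT 3, HET 2, KO 1 or KO 2 (adjusted p from 0.0507 to 0.103), where 0 rose, and 2 rose without KO 3. Among the falls, calls were lost without WT 1 or WT 3 for Eif2b3 (0.0633, 0.0516), without any WT array or KO 2 for Eif3c (0.0645 to 0.0912), without WT 1, WT 2, KO 2 or KO 3 for Eif2ak2 (0.0669 to 0.105), and without any single array other than WT 3 or KO 3 for Eif5a2 (0.0563 to 0.152). Without KO 1 the number that fell was 13, and it was 2 without KO 2, 1 without WT 1, 2 without WT 2 and 3 without WT 3.

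Of 22 endoplasmic reticulum chaperone genes 4 fell, 0 rose and 18 did not pass (4 when adjusted over the list alone), with a median of -0.11. The list shifted down by camera at the preset correlation (adjusted p = 0.0256, against adjusted p = 0.787 with an estimated correlation). By fry against no change it shifted down as well (adjusted p = 0.00976). Sel1l, which serves the disposal of misfolded proteins, fell by 0.60 ± 0.06 (adjusted p = 0.00103), the transcription factor Xbp1 by 0.50 ± 0.08 and the disulfide isomerase Pdia4 by 0.33, although another, dimmer probe set of Pdia4 stood at -0.03. Dnajb9 fell by 0.34 (adjusted p = 0.0419), a call lost without any of WT 1, WT 2, WT 3, HET 2, KO 2 or KO 3, with adjusted p from 0.0558 to 0.133. The list's camera adjusted p was 0.206 after quantile normalization, 0.0906 without WT 3 and 0.0701 without KO 1.

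Stress and growth lists moved in both directions or not at all by camera. Fry in either direction, a test against no change, passed for many lists and does not set these apart. Of 36 genes of the integrated stress response 7 rose, 9 fell and 20 did not pass (9 and 10 when adjusted over the list alone; median -0.05, mean -0.00, camera upward with adjusted p = 0.962, fry in either direction 2.87e-07). The serine synthesis gene Psat1 (-0.41), the alanine transaminase gene Gpt2 (-0.57) and the tRNA ligase gene Yars (-0.39) fell, and the transcription factor Ddit3 rose by 0.38. In that list the number that rose was 2 without HET 1, WT 3 or KO 2, 3 without HET 2 or WT 1, 4 without HET 3 and 1 without WT 2, and the number that fell was 5 without WT 1 or WT 3 and 4 without WT 2. Of 36 hypoxia genes 4 rose, 6 fell and 26 did not pass (5 and 8 when adjusted over the list alone; median -0.04, camera adjusted p = 0.962, fry in either direction 4.64e-07). Hexokinase 2 (Hk2, 0.61) and the corepressor Rcor2 (0.97) rose, as did Ddit4 (0.84) and Stc2 (0.27), named after their values were seen, and Car12 (-1.01) and Selenbp1 (-0.53) fell. Ddit4 lost its call without WT 2 (adjusted p = 0.0711) and Stc2 without any single array other than HET 3 or KO 1 (0.0512 to 0.111). Without WT 2 the number that rose was 2 and without WT 1 the number that fell was 3. Of 24 p53 targets 5 rose, 1 fell and 18 did not pass (5 and 1 when adjusted over the list alone; median -0.01, mean 0.09, camera upward with adjusted p = 0.258). Plk2 (0.95 ± 0.12), Psrc1 (0.41), Btg2 (0.56), Phlda3 (0.49) and Sesn2 (0.31) rose, and the fall of Tigar (-0.28) was absent without WT 1, WT 2, WT 3, HET 2, KO 1 or KO 3, where 0 fell (adjusted p from 0.0514 to 0.117). Sesn2 lost its call without WT 1, WT 3, HET 2, KO 1 or KO 2 (0.0523 to 0.102). Tigar and Sesn2 were named after their values were seen.

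Of 33 cell division genes 2 fell, 0 rose and 31 did not pass (0 and 0 when adjusted over the list alone; median -0.04, camera adjusted p = 0.682). Bub1 stood at -0.32 and Kif11 at -0.23, and 0 fell without WT 1, WT 2 or KO 2, 1 fell without WT 3, and 1 rose without HET 2 or KO 1. The adjusted p of Bub1 was 0.0778 without WT 1, 0.0677 without WT 2 and 0.0517 without KO 2, and that of Kif11 was 0.055 to 0.0865 without any WT array or KO 2. Cholesterol synthesis had 6 of 19 genes lower, 0 higher and 13 not past the test (6 when adjusted over the list alone; median -0.19, camera adjusted p = 0.123), among them Hsd17b7 (-0.48) and Fdft1 (-0.41). There, 2 fell without WT 1, WT 2 or KO 2. Interferon response genes gave 3 falls and 0 rises among 14, with 11 not past the test (3 when adjusted over the list alone; median 0.01, mean -0.09, camera downward with adjusted p = 0.649). These were Rsad2 (-0.73), Ifi35 (-0.32) and Eif2ak2 (-0.51), and 1 fell without WT 1, WT 2 or KO 2. Rsad2 lost its call without WT 2 (adjusted p = 0.0536) or KO 2 (0.0547), Ifi35 without WT 1 (0.0731), and Eif2ak2 without WT 1, WT 2, KO 2 or KO 3 (0.0669 to 0.105). Of 7 genes of the inflammasome and inflammation 1 rose, 1 fell and 5 did not pass (1 and 1 when adjusted over the list alone; median 0.15, camera adjusted p = 0.698). Nfkbia, an inhibitor of NF-kappa-B, stood at 0.32 and Tnfaip3 at -0.39. The rise was lost without HET 2 or any single WT or KO array, with 0 rising (adjusted p from 0.0545 to 0.128), and the fall without WT 2, with 0 falling (0.0693). The single testable gene of the ribonuclease A family, Ang6, stood at -0.03 (camera adjusted p = 0.962), and 0 members passed by limma at the adjusted or the unadjusted level.

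Markers of tissues next to the yolk sac also differed between arrays. Of 13 genes of the embryo proper 2 rose, 0 fell and 11 did not pass (1 rose when adjusted over the list alone; median 0.23). Hoxb9 rose by 0.66 ± 0.12 (adjusted p = 0.00677) and En1 by 0.29 (adjusted p = 0.0479), a call lost without any single array other than WT 3 or KO 1 (0.0652 to 0.116). The camera adjusted p was 0.0256 at the preset correlation (adjusted p = 0.787 with an estimated correlation), 0.145 after quantile normalization, 0.116 without WT 2, 0.0923 without KO 2 and 0.0716 without KO 3. By fry against no change it was 0.157. The number that rose was 5 without KO 1 and 1 without WT 1, WT 2, KO 2 or any HET array. Trophoblast genes had a median of 1.03 with 0 of 7 past the test and 0 when adjusted over the list alone (camera adjusted p = 0.228). Ascl2 stood at 1.03 (adjusted p = 0.162), Tfap2c at 1.09 and Syna at 1.19, and 2 rose without KO 1. The trophoblast mean was 7.52 to 7.59 on WT arrays, 6.58, 7.60 and 7.86 on HET, and 7.59, 8.05 and 8.82 on KO.

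The labels state that maternal tissue was excluded during dissection. Of 13 genes of the decidua, the maternal lining, 2 rose, 0 fell and 11 did not pass (2 when adjusted over the list alone; median 0.20, camera adjusted p = 0.146), and both, Hand2 (0.45) and the muscle filament gene Des (0.64 ± 0.11), are also expressed outside the decidua. Without KO 1, 4 rose. The decidua mean was 7.81 to 7.94 on WT arrays, 6.89, 7.55 and 7.50 on HET, and 8.27, 7.85 and 8.01 on KO. Adult blood genes had 0 of 2 members past the test and 0 when adjusted over the list alone (median 0.19, camera adjusted p = 0.406). Of the 4 sex-linked transcripts 0 passed, also when adjusted over the list alone (median -0.57, mean 0.09, camera upward with adjusted p = 0.962). Xist stood at 2.15 (adjusted p = 0.354).

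Among the 61 tested genes near Rnh1 on its chromosome, 5 rose, 9 fell and 47 did not pass (5 and 9 when adjusted over the list alone; median -0.01, camera upward with adjusted p = 0.928). Of all genes tested 23.5% passed, so these counts do not set the neighbours apart. Nadsyn1 (-0.67 ± 0.11), Chid1 (-0.50) and Ap2a2 (-0.26) fell, and Tssc4 rose by 0.39. The other rises were Deaf1 (0.25), Dusp8 (0.46), Ifitm1 (0.53) and Ifitm2 (0.48), named after their values were seen. Deaf1 lost its call without WT 1 (adjusted p = 0.0661), Dusp8 without WT 2 (0.056), Ifitm1 without WT 1 (0.0778) or WT 3 (0.0679) and Ifitm2 without any WT array (0.0639 to 0.0987). The number that rose was 9 without KO 1, 2 without WT 1 and 3 without WT 2 or WT 3, and the number that fell was 3 without WT 1 and 4 without WT 2.

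**Figure D3:**
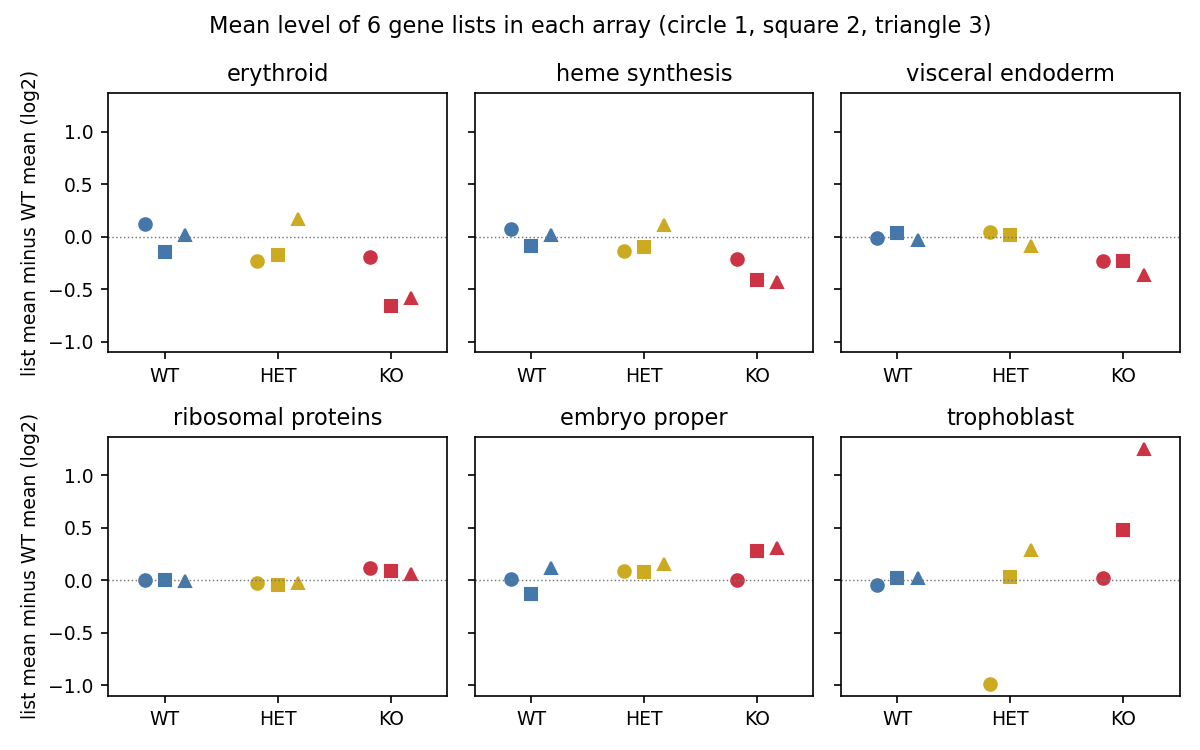
Mean log2 signal of 6 gene lists on each array minus the mean over WT arrays (y axis) by genotype (x axis), with circles, squares and triangles for arrays 1, 2 and 3. Erythroid means are 9.07, 8.60 and 8.68 on the KO arrays against 9.12 to 9.38 on WT, and trophoblast means span 7.59 to 8.82 within KO.

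HET against WT asked what differed when 1 copy of Rnh1 was missing. Rnh1 itself was 64.9% of its WT level, and no other gene passed either. Utp18, a factor of ribosomal RNA processing, stood at 9.46 ± 0.15 in HET and 10.12 ± 0.04 in WT (log2 -0.66 ± 0.09, SE, n = 3, limma adjusted p = 0.627), with KO at 9.53 ± 0.13. Brix1, another ribosome assembly factor, stood at -0.35 ± 0.08, and Hamp2 at 0.29 ± 0.07, Efhc2 at 0.66 ± 0.16 and Zfp384 at 0.21 ± 0.05 (adjusted p = 0.939 each). None of these passed.

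By limma 0 of 13207 genes passed, 327 had an unadjusted p under 0.05 against 660 by chance, and limma with a trended, robust prior also gave 0. With only the 2 genotypes compared 601 had an unadjusted p under 0.05, and again 0 passed. Small p-values were thus fewer than chance gives, and Rnh1 itself did not pass. The 0 therefore does not show that HET and WT are alike. With array weights 6 genes passed, all lower in HET. These were Rnh1 (-0.64), Utp18 (-0.64), the steroid synthesis genes Cyp11a1 (-2.34) and Star (-2.20), Plat (-1.30) and Srgn (-1.49). Without WT 2, 5 genes passed, all lower in HET, namely Fst (-3.04), the basement membrane genes Lama1 (-1.77), Nid1 (-1.27) and Col4a2 (-0.96), and Srgn (-1.69). Without KO 1 only Rnh1 passed, and without WT 2 and KO 1 together Fst, Lama1, Srgn and Rnh1 did. Apart from Rnh1 and Utp18, these genes were named after their values were seen. Over all arrays Fst stood at 9.04 ± 2.11 in WT, 7.22 ± 0.16 in HET and 7.26 ± 0.33 in KO, and Lama1 at 10.72 ± 1.03, 9.53 ± 0.11 and 9.48 ± 0.23 (SD, n = 3).

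Among the lists 5 of 26 passed camera at the preset correlation in HET against WT, in each case with 0 members past the test by limma, also when adjusted over the list alone, and fry passed 0 lists. Cell division genes were lower (median -0.06, adjusted p = 0.00674, against adjusted p = 0.540 with an estimated correlation), with an adjusted p of 0.0636 without WT 3. Neighbours of Rnh1 were higher (median 0.04, adjusted p = 0.00718, against adjusted p = 0.153 with an estimated correlation), with an adjusted p of 0.0809 with no filter. Embryo proper genes were higher (median 0.14, adjusted p = 0.00977, against adjusted p = 0.566 with an estimated correlation), with adjusted p of 0.333 without WT 2 and 0.141 without HET 3. That adjusted p was 0.0737 after quantile normalization and 0.341 without WT 2 and KO 1 together. Ribosomal protein genes were lower (median -0.03, adjusted p = 0.0435, against adjusted p = 0.540 with an estimated correlation), a call lost without any array but WT 2 or HET 3, with adjusted p from 0.0511 to 0.365. Decidua genes were lower (median -0.22, adjusted p = 0.0435, against adjusted p = 0.540 with an estimated correlation), with adjusted p of 0.531 without HET 1, 0.146 without WT 3, 0.0547 without KO 1, 0.0694 without KO 2 and 0.0548 without KO 3. The number of lists that passed was 8 without WT 2, 2 without WT 3, 3 without HET 1, 9 without HET 3 and 3 without KO 1, KO 2 or KO 3. Erythroid (median -0.08, adjusted p = 0.0941) and visceral endoderm genes (median 0.02, adjusted p = 0.709) did not pass.

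KO against HET asked what differed when the remaining copy of Rnh1 was missing as well. Hgd fell by 2.07 ± 0.19 (log2, SE, n = 3 per genotype, limma adjusted p = 0.000747), from 9.66 ± 0.29 to 7.59 ± 0.28 (SD), the alcohol dehydrogenase Adh1 by 1.81 ± 0.20 and Gja5 by 1.73 ± 0.19. Jun rose by 1.55 ± 0.15, Rnu3a by 1.79 ± 0.17, Ccn1 by 1.51 and Edn1 by 1.34 ± 0.10. Slc27a2 (-1.71), Slc22a2 (-1.66), Keg1 (-1.59), Clec2h (-1.57), Serpina1c (-1.53 ± 0.31) and Akr1c19 (-1.51) were also among the largest falls, and Vaultrc5 (1.47), Ctla2a (1.44 ± 0.21), Sox11 (1.39) and Ctxn1 (1.24 ± 0.13) among the largest rises.

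Prl8a2, a prolactin family gene of the decidua, rose by 2.69 ± 0.81 (adjusted p = 0.0431), with 9.40, 8.90 and 10.72 on the WT arrays, 6.50, 9.75 and 7.18 on HET and 10.40, 9.76 and 11.34 on KO. That call was lost without HET 1 (adjusted p = 0.144), HET 3 (0.121), KO 1 (0.0749), KO 2 (0.059), KO 3 (0.124) or WT 1 (0.0655). It was also lost with no filter (0.0595), the replicate block (0.0549), the trended and robust prior (0.0531) or array weights (0.0747). The same held with only the 2 genotypes compared (0.0659) or the Eif2s3y covariate (1.84, adjusted p = 0.144). Apela rose by 1.47 and lost its call without HET 1 (adjusted p = 0.0642) or HET 3 (0.0523) or with the Eif2s3y covariate (0.0603). By limma 2875 of 13207 genes (21.8%) differed between KO and HET, 1079 higher and 1796 lower (62.5% lower), of which 159 and 408 differed by at least 1.5-fold and 24 and 74 by at least 2-fold. With each array centred on its median, 698 were higher and 1720 lower (71.1% lower), against 1475 and 1916 after quantile normalization (56.5% lower) and 1328 and 1887 with cyclic loess (58.7% lower). Without HET 1 the count was 1508, and without HET 2 it was 1557.

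Of the lists, 6 passed camera at the preset correlation in KO against HET. Among these, visceral endoderm (adjusted p = 0.0162), ribosomal proteins (0.00251) and decidua (0.00938) also passed fry against no change. Visceral endoderm genes had 16 of 38 lower and 0 higher (16 when adjusted over the list alone; median -0.17, adjusted p = 1.37e-04, against adjusted p = 0.673 with an estimated correlation). Erythroid genes had 10 of 34 lower and 0 higher (12 when adjusted over the list alone; median -0.42, adjusted p = 8.33e-04, against adjusted p = 0.723 with an estimated correlation, 0.135 by fry against no change and 0.0809 without HET 3). Heme synthesis had 7 of 15 lower and 0 higher (8 when adjusted over the list alone; median -0.28, adjusted p = 0.00377, against adjusted p = 0.673 with an estimated correlation, 0.0709 by fry against no change and 0.0809 without HET 3). Ribosomal protein genes had 11 of 57 higher and 0 lower (10 when adjusted over the list alone; median 0.09, adjusted p = 7.74e-06, against adjusted p = 0.259 with an estimated correlation). Decidua genes had 3 of 13 higher and 0 lower (3 when adjusted over the list alone; median 0.33, adjusted p = 0.00377, against adjusted p = 0.259 with an estimated correlation), the 3 being Hand2 (0.33), Des (0.77) and Prl8a2. With the filter at the array median the decidua median was 0.20. Extraembryonic mesoderm genes had 5 of 29 higher and 1 lower (5 and 1 when adjusted over the list alone; median 0.08, adjusted p = 0.0434, against adjusted p = 0.673 with an estimated correlation and 0.0899 by fry against no change). Hand1 (0.72), Hand2, Twist1 (0.64) and, named after their values were seen, Tbx20 (0.37) and Foxf1 (0.30) rose, and Postn (-0.28) fell. In that comparison Postn lost its call without WT 1, WT 3, KO 2, KO 3 or any HET array (adjusted p from 0.0567 to 0.114), Foxf1 without HET 1 (0.0734) or HET 3 (0.0608) and Tbx20 without HET 1 (0.057) or KO 2 (0.0544). Postn lost it also with no filter (0.0595), centring (0.0529), the replicate block (0.0552), only the 2 genotypes (0.0796) or the Eif2s3y covariate (0.119). Foxf1 lost it also with centring (0.0648), the mean of a gene's probe sets (0.0713) or only the 2 genotypes (0.0565).

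The mesoderm list lost its call by camera without HET 3 (adjusted p = 0.105), KO 1 (0.0866) or KO 2 (0.0925). The list lost it also with the mean of a gene's probe sets (0.0514) or without WT 2 and KO 1 together (0.0879). Its median was 0.03 without HET 3, 0.13 without HET 2 and 0.14 after quantile normalization. Without HET 1 the number of its members that rose was 3, and without WT 2 and KO 1 it was 8. In the same comparison the number of erythroid genes that fell was 18 without KO 1, 5 without KO 2 and 6 without KO 3 or any HET array, that of heme synthesis genes was 4 without HET 3 or KO 2, and the number of ribosomal protein genes that rose was 7 without HET 2, 19 with cyclic loess and 17 with a trended, robust prior. The visceral endoderm median was -0.10 without KO 3, where 1 member rose, and -0.11 with the Eif2s3y covariate, and 1 rose with array weights. Without HET 3 the number of lists that passed was 3. With the Eif2s3y value as a covariate, chosen after the data were seen, 4 erythroid and 3 heme synthesis genes fell, and the mesoderm list did not pass (adjusted p = 0.0984).

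Set against the 6 WT and HET arrays as 1 group, the KO arrays differed in 4100 of 13207 genes (31%), 1575 higher and 2525 lower (61.6% lower). Slc22a2 fell by 1.68 ± 0.11 (adjusted p = 7.95e-05) and Edn1 rose by 1.34 ± 0.08 (adjusted p = 5.6e-05), log2 with SE. Among the 4100 genes 164 were higher and 431 lower by at least 1.5-fold, and 28 were higher and 70 lower by at least 2-fold. Centring each array on its median gave 967 higher and 2775 lower (74.2% lower), quantile normalization 2052 and 2488 (54.8% lower) and cyclic loess 1888 and 2429 (56.3% lower).

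The comparisons of KO with WT and with HET share the KO arrays. In them 817 genes were called higher in both, 1567 lower in both and 0 in opposite directions, while independent lists would share 89.2 and 273. The 100 simulations drew every array, KO included, as noise without a difference. Their 0 shared calls therefore do not show how many calls the shared KO arrays add. Fold changes across genes, which are not independent replicates, correlated with r = 0.906 against 0.5 simulated, the value that sharing a group gives by itself. Their covariance was 0.0746 against 0.00629 simulated, a difference of 0.0683. The 3 KO arrays are too few to be divided between the comparisons with at least 2 in each, so part of the excess may come from the shared arrays. Without WT 1, WT 2, HET 1 or HET 2 the number called in the same direction in both was 1440, 1578, 1348 or 1423. For KO and HET each against the shared WT arrays, 0 genes were called in both, since 0 passed in HET, r was 0.254 against 0.5 simulated, and the covariance was 0.00917 against 0.00628 simulated, a difference of 0.00289.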

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

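The patterns weighed here were picked after the list counts and medians had been seen, and the bounds of the tests for the share of erythroid cells, the share of endoderm cells and compression of the endoderm list were replaced after their values had been seen. The other bounds were set before the tested value was computed, and the small nucleolar RNA, host gene and endoderm epithelium lists were written after the data were examined. Among probe sets outside the gene comparisons, 201 of 2037 tested probe sets that name no gene passed in KO against WT by limma (110 higher, 91 lower), against 0 in HET against WT, where 65 had an unadjusted p under 0.05. Among probe sets that name several genes 79 of 857 passed (55 higher, 24 lower), against 0 in HET against WT, where 19 had an unadjusted p under 0.05. Both counts stand here because they are signals in data that the gene comparisons did not use.

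Splits of the arrays bear on the gene counts. For KO against WT, 10 splits of the 6 arrays are too few for a share under 0.05, the real split giving 3101 genes (reached by 1 split, itself) and the highest other 0. For KO against HET the 10 splits are again too few, with 2875 in the real split (reached by 1 split, itself) and 0 in the highest other. The same holds for HET against WT, where the real split gave 0 and was thus matched by all 10 splits, and the highest other gave 1. For KO against the 6 other arrays the share was under 0.05, since 1 of 84 splits, the real one, reached 4100 genes and the highest other gave 1. Every other split groups KO arrays with WT or HET arrays, which widens the spread and lowers the count. The share also takes the arrays as independent samples, which the labels do not state, so chance is not excluded.

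Of 34 erythroid genes 16 fell in KO against WT and 0 rose, with a median of -0.54 (camera adjusted p = 1.47e-04, against adjusted p = 0.787 with an estimated correlation). Compression left in the deposited values of the KO arrays is argued against as the cause. After quantile normalization the median was still -0.51, with a 95% bootstrap interval of -0.58 to -0.21. That interval resamples genes and not arrays, and the estimated correlation among members was 0.645. It is thus too narrow, and the argument rests on the median. The deposited values had already been normalized between arrays by RMA. A distortion made by that step would remain, and it was not tested. A smaller share of erythroid cells cannot be told apart from lower expression per cell, because the 94.1% of members below 0 (32 of 34) restate the pattern and either would give them. Members ranged from -1.27 for Rhag to 0.19, with Gata1 at -0.19 and Klf1 at -0.43. Litter and developmental stage, which the labels do not give, were not tested.

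Of 38 visceral endoderm genes 14 fell in KO against WT and 1 rose, with a median of -0.17 (camera adjusted p = 1.47e-04, against adjusted p = 0.787 with an estimated correlation). Compression left in the deposited values is argued against as the whole cause. After quantile normalization the list still passed camera (adjusted p = 2.52e-04, and 1.37e-06 to 0.00151 over the alternatives that were run on list tests at the preset correlation). Its median was then -0.13 (95% bootstrap interval -0.25 to -0.09). Part of the shift is not excluded, and a distortion made by the RMA step itself was not tested. A smaller share of endoderm cells cannot be told apart from lower expression per cell, because the median of 14 epithelial, uptake receptor and transcription factor genes of the list, -0.11, had an interval of -0.17 to -0.04 that reached the list median. An earlier bound, the median of the members that fell, was dropped because those members were picked for having fallen. Both intervals resample genes and not arrays, with an estimated correlation of 0.341 among members of the list. Litter and developmental stage were not tested here either.

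Of 43 small nucleolar RNAs 20 rose in KO against WT and 0 fell, with a median of 0.39 (camera adjusted p = 1.23e-10, against adjusted p = 0.0937 with an estimated correlation). A drift of genes of like signal level is argued against, since that median lay at percentile 100 of 10000 random lists matched on mean level, of which the central 95% spanned -0.09 to 0.08. The class was picked after its values were seen, and random genes do not move together as its members do. The percentile thus bears on drift only and is no measure of chance. Compression left in the deposited values is argued against too, as the median after quantile normalization was 0.45 (95% bootstrap interval 0.32 to 0.59). That interval also resamples genes and not arrays, with an estimated correlation of 0.159. Here too a distortion made by the RMA step itself was not tested. More transcription of the host genes cannot be told apart from other causes, because the host gene median of 0.0669 had an interval of -0.05 to 0.20 that reached the required 0.19, and was 0.02 without KO 3 and 0.11 without KO 1. Slower decay of these RNAs, or a difference in how short RNAs were recovered from the samples, may also lie behind it and was not tested.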

How the results depend on the processing

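Leaving out WT 2 and KO 1 together and the Eif2s3y covariate were tests chosen only after the data had been seen. List tests were not run under the filter at the array median, centring, cyclic loess, the trended and robust prior, array weights or only the 2 genotypes. Of the calls on named genes and list tests, 0 reversed direction under the alternatives each was run under. The KO against WT medians of several lists that did not pass camera changed sign, among them that of small nucleolar RNA host genes (-0.00 with arrays centred on their medians). Named genes were not run under the alternatives of at least 1.5-fold and of an adjusted p under 0.1. Under the others, of 89 named genes past the test in KO against WT 61 kept their call throughout and 28 lost it under at least 1, and of 19 in KO against HET 17 kept it and 2 lost it. With array weights, whose fit stopped short of convergence, the counts were 5753 for KO against WT and 6 for HET against WT, 3660 calls were shared between KO against WT and KO against HET, and Rnh1 in HET against WT (-0.64) passed; the cause was not tested. Requiring a change of at least 1.5-fold gave 608 for KO against WT, 567 for KO against HET, 595 for KO against WT and HET and 457 shared calls, since it adds a condition. Without WT 2 and KO 1 the HET against WT count was 4, Rnh1 (-0.60) passed and 8 lists passed there; the cause was not tested. The Eif2s3y value was not balanced between the genotypes. With it as a covariate KO against HET gave 1739, the shared calls were 1582 and 2 lists passed in HET against WT. The cause was not tested. The number of lists that passed in HET against WT was 13 with no filter, 3 after quantile normalization and 0 by fry, which passed 4 in KO against WT. An estimated correlation passed 0 lists in KO against WT, 0 in HET against WT and 0 in KO against HET; the cause was not tested. With 1 array left out the counts ranged from 1669 to 3842 for KO against WT, 0 to 5 for HET against WT, 1508 to 3149 for KO against HET, 3213 to 4298 for KO against WT and HET and 1348 to 2742 for shared calls. Lists that passed ranged from 5 to 7, 2 to 9 and 3 to 7 in KO against WT, HET against WT and KO against HET. Rnh1 ranged from -3.84 to -3.55, -0.65 to -0.60 (past the test without KO 1, at -0.62) and -3.22 to -2.93. With the replicate number as a block the counts were 3131, 0, 2853 and 4120, with 2796 of the 3101 calls of KO against WT shared, and 3 lists passed in HET against WT. Deviations of arrays with the same number correlated with r from -0.26 to 0.42, not all above 0.1, with 0.18 to 0.42 for number 3. With 3 arrays per genotype these values cannot tell whether the numbers pair the samples. Signal over background limits dim genes, and 6726 were not tested.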

Other observations

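All gene lists of this part were chosen after the data had been examined, so their tests describe these arrays only. On the same arrays the mean of the visceral endoderm list, of which 14 of 38 fell, was 11.23 to 11.30 in WT and 10.90 to 11.03 in KO. Of 31 genes of amino acid breakdown 27 fell in KO against WT, 0 rose and 4 did not pass, with a median of -0.58 (camera adjusted p = 4.03e-13 at the preset correlation, against adjusted p = 0.0937 with an estimated correlation). With array weights, without KO 1 or without WT 2 and KO 1, 2 of them rose. Kynu, an enzyme of tryptophan breakdown, fell by 1.21 ± 0.11 (log2, SE, n = 3 per genotype, limma adjusted p = 0.00102), Aass, which starts lysine breakdown, by 0.95 ± 0.10 and Acat1 by 0.93 ± 0.08. Of 26 genes of fatty acid oxidation 15 fell, 0 rose and 11 did not pass (median -0.38, adjusted p = 1.06e-08, against adjusted p = 0.138 with an estimated correlation), among them Acaa2 (-0.69 ± 0.07), Hadhb (-0.61 ± 0.08) and Ehhadh (-1.06 ± 0.15). Solute carriers had 80 of 267 lower and 12 higher (median -0.13, adjusted p = 9.68e-05, against adjusted p = 0.138 with an estimated correlation). The number that rose was 18 without KO 1, 6 without HET 1, HET 2 or KO 2, 3 without WT 1 and 5 without WT 2. With arrays centred on their medians 4 rose and 96 fell, and with array weights 34 rose and 120 fell. Respiratory chain genes had 20 of 78 lower and 0 higher (median -0.11, adjusted p = 9.07e-04, against adjusted p = 0.162 with an estimated correlation). The median was -0.05 after quantile normalization or cyclic loess and -0.17 with arrays centred on their medians. After quantile normalization 13 fell and 3 rose, with cyclic loess 13 fell and 2 rose, and with array weights 28 fell and 6 rose. There, 1 rose without KO 1, without WT 2 and KO 1 or with the trended and robust prior. The number that fell was 6 without WT 1, 7 without WT 2, 12 without WT 3, 13 without KO 2 and 9 without KO 3. Of 14 genes of endoderm epithelium and factors 0 passed by limma (median -0.11, camera adjusted p = 0.232), and 2 fell with array weights, 1 fell with arrays centred on their medians, the trended and robust prior, the replicate block, without WT 2 or without WT 2 and KO 1, and 1 rose without KO 2.

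Immediate early genes, which cells switch on within minutes of a stimulus, had 16 of 28 up and 1 down in KO against WT (median 0.37, adjusted p = 5.95e-09, against adjusted p = 0.056 with an estimated correlation). Srf (0.53 ± 0.06), Ier5 (0.60 ± 0.10), Jund (0.61 ± 0.10) and Gadd45b (1.06 ± 0.18) rose and Klf10 (-0.27) fell, and 0 fell without any single array other than WT 3 or HET 3. Genes of the actin cytoskeleton and targets of YAP had 13 of 28 up and 1 down (median 0.22, adjusted p = 6.41e-06, against adjusted p = 0.101 with an estimated correlation), with rises of Dbn1 (0.62 ± 0.06), Flnc (0.65 ± 0.06), Amotl2 (0.65 ± 0.07) and Tead2 (1.07 ± 0.15) and a fall of Myl9 (-0.44). There, 7 rose without WT 1 and 8 without WT 2 or KO 2 or with arrays centred on their medians, and 0 fell without any single array other than HET 3 or KO 2. Small nucleolar RNAs had 20 of 43 up and 0 down (median 0.39, adjusted p = 1.23e-10, against adjusted p = 0.0937 with an estimated correlation), among them Snora62 (0.86 ± 0.09), Snord118 (0.95 ± 0.19) and Snord55 (0.69 ± 0.08). Their mean was 8.50 to 8.67 on WT arrays, 8.41 to 8.52 on HET and 8.94 to 9.15 on KO. In HET against WT 0 of 43 passed by limma (1 at an unadjusted p under 0.05), and the list lay lower by camera (median -0.10, adjusted p = 4.24e-04, against adjusted p = 0.471 with an estimated correlation). Of 18 host genes of these RNAs 5 rose and 0 fell, namely Snhg5 (0.81 ± 0.09), Gas5 (0.42), Snhg17 (0.35), Eif4a2 (0.27) and Snhg15 (0.22). Their median was 0.07 (-0.00 with arrays centred on their medians; camera adjusted p = 0.0504), and 1 rose without WT 1, 2 without WT 2, 1 without WT 3 and 3 without KO 1. Gas5 lost its call without any WT array (adjusted p from 0.0507 to 0.0511), Snhg17 without WT 1 (0.056) or WT 3 (0.0528), and Eif4a2 and Snhg15 each without 6 of the 9 arrays (0.0507 to 0.103 and 0.0582 to 0.12). MicroRNA genes, a list caught by symbol that also holds the host transcripts Mir17hg (0.71, past the test) and Mir99ahg, had 11 of 84 up and 0 down (median 0.24, adjusted p = 5.39e-09, against adjusted p = 0.162 with an estimated correlation), and 26 rose without KO 1, 21 without WT 2 and KO 1 and 32 with array weights. In HET against WT 0 of the 84 passed by limma (5 at an unadjusted p under 0.05), and the list lay higher by camera (median 0.17, adjusted p = 3.57e-11, against adjusted p = 0.471 with an estimated correlation). In KO against HET 9 rose and 0 fell (median 0.06, adjusted p = 0.00246, against adjusted p = 0.469 with an estimated correlation).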
